A study of Rattus norvegicus with 9 samples.

How the data were processed

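RNA was sequenced from 9 samples of 50B11 cells, an immortalized line made from embryonic rat dorsal root ganglion neurons. Per the labels, 3 samples were untreated, undifferentiated cells, and the maintenance medium of the line held 10% fetal bovine serum. The harvest day of the undifferentiated samples is not given in the labels. Their columns carry the code 2D and those of the other samples 7D, and what 2D stands for is not stated. The other samples received 10 µM forskolin, which raises cAMP by activating adenylyl cyclase, in medium with 1% serum, starting 24 h after plating. From 17 h after forskolin they also received a growth factor at 50 ng/ml every 2 days until harvest on day 7 in vitro, mouse NGF in 3 samples and human GDNF in 3 samples. These groups are called undifferentiated, FSK_NGF and FSK_GDNF. No group received forskolin without a growth factor, so forskolin and growth factor change together in both comparisons against undifferentiated cells. Serum and time in culture may change with them, as the labels give neither for the undifferentiated samples themselves. The labels do not say whether the 3 samples of a group came from separate cultures or plating days, so the p-values measure the spread between these samples, which may be technical.

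Libraries were stranded total RNA libraries with ribosomal RNA depletion, sequenced on a NextSeq 500, per the labels' protocols. The submitters' processing notes name cutadapt 1.8.1, FastQC, STAR 2.5.3a and DESeq2. The genome build, the annotation and the settings of read counting are not given in the sources used here, so no coordinates are printed. Genes carry rat Ensembl identifiers and symbols as the deposited tables pair them. The authors deposited 1 table of RPKM values (reads per kilobase of gene, scaled to the size of the library) with 1 column per sample, and 3 tables of pairwise comparisons. Per the file headers, those comparison tables hold the authors' log2 fold changes with standard errors and adjusted p-values, in columns named as DESeq2 names them. The values in them show that only genes at an adjusted p-value of 0.05 or less were listed by the authors.

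Columns were matched to samples by name. The column codes of the differentiated samples give a replicate number and the letters NF or GF, which were read as the initials of NGF plus forskolin and of GDNF plus forskolin. The letters could also be read as the ends of the other factor's name. Under that reading, FSK_NGF and FSK_GDNF would change places and every difference between them would change sign. All columns of the RPKM table belong to these 9 samples.

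RPKM values are not counts, so genes were tested on a log scale. Because the authors' RPKM values come from whole reads, the reads behind each value could be worked out from the ratios between the low values of a gene in different libraries. Whole reads were recovered for 22481 of the 22502 genes above 0 in any library (99.907%), within a tolerance of 1e-05. Genes without recovered reads counted as 0 in the read totals and in the shares of reads. The search tried multipliers of up to 20000, so very abundant genes may be among those left out. Their means lay within 1% of the authors' deposited mean counts for 99.73%, 99.74% and 99.91% of the genes with recovered reads in the 3 deposited comparison tables. Recovered reads ranged from 11327919 (FSK_GDNF replicate 3) to 27333390 (undifferentiated replicate 1) per library. The recovered reads were used for depth, read counts and shares of reads, feature lengths, the comparison of replicates and 1 added alternative test, and the main test used the RPKM values. Pairs of libraries of 1 group differed beyond sampling noise (chi-square per degree of freedom from 9.249 to 47.527), so none was taken for a repeat deposit of another library, which does not show that they came from separate cultures.

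The main test was limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.5), with the 3 groups as terms, all 9 samples in 1 fit and a mean-variance trend. It ran on the 14613 genes with a mean RPKM of at least 0.5 over the 9 samples. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Fold changes are on the log2(RPKM + 0.5) scale, which understates the change of low genes. Lists of genes were tested with limma's camera at a preset correlation of 0.01, and again with the correlation estimated from the data, with Benjamini-Hochberg adjustment over 35 lists in 3 comparisons (105 tests). Where a symbol stands on more than 1 row, the row with the highest mean RPKM was used for the lists.

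The groups, the test, the filter, the pseudocount, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names, in each comparison, the 6 largest rises and 6 largest falls among called genes with a mean RPKM of at least 2 and no overlap between the groups' values. It passes over symbols that begin with LOC, RGD, AABR, ENSRNOG, Mir, Snor or AC and digits, and symbols with no letters. Small nucleolar RNA symbols in capitals and genes whose symbol was given as missing were also passed over, which the rule as first written did not spell out. Other names made from contigs or sequence accessions were not passed over. It also names up to 4 called members of each list with the largest change, or, where no member is called, the 2 with the highest mean RPKM. It names 18 genes in every comparison, among them the receptors of NGF and GDNF. Any other gene named was chosen after its values were seen, which is stated there.

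The test was tried on simulated log2 values made from the real means and residual spread, with 200 of 14613 genes changed. In the comparison of FSK_NGF with undifferentiated cells, 19.7%, 85.1% and 92.5% of the genes changed by 0.5, 1 and 2 on the log2 scale were recovered, with 10 false calls among 142. In the comparison of FSK_GDNF with undifferentiated cells the shares were 18.2%, 73.1% and 89.6%, with 6 false calls among 127. In the comparison of FSK_GDNF with FSK_NGF they were 28.8%, 71.6% and 97.0%, with 9 false calls among 141. Far more genes were called in the data (5372, 6088 and 3420 in these comparisons) than were changed in the simulation. The adjusted p depends on that number, so these shares do not carry over to the data.

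The alternatives were pseudocounts of 0.1 and 1, no filter and a filter at a mean RPKM of 1, libraries rescaled to a median log2 ratio of 0, no mean-variance trend, a fit on the compared groups only, the replicate number as a block, each library left out in turn and a 2-fold threshold. The authors' deposited tables served as a further comparison. Alternatives chosen after seeing the data were limma's voom on the recovered reads, leaving out features of 300 nt or less, removing each library's trend with feature length (lowess, span 0.3) and, for the lists, leaving out FSK_GDNF replicate 3. Feature length was taken from the ratio of reads to RPKM and is therefore the length the authors' RPKM values imply. GC content was not analysed here because no genome was used. How the authors treated reads that map to several copies is not given in the sources used here, so values of histone, ribosomal protein, small RNA and other multi-copy genes are uncertain. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 scipy 1.17.1 and matplotlib 3.10.9.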

Results

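RNA from 9 samples of the rat sensory neuron line 50B11 was measured by sequencing, to compare expression between growth conditions. There were 3 undifferentiated samples, 3 samples differentiated with forskolin and NGF (FSK_NGF) and 3 differentiated with forskolin and GDNF (FSK_GDNF). NGF and GDNF are growth factors that maintain different classes of nociceptor, the sensory neurons that report pain. Recovered reads numbered 27333390, 25007276 and 25996209 in undifferentiated replicates 1 to 3 and 20861589, 17389818 and 19431508 in the FSK_NGF replicates. They numbered 22854973, 20867228 and 11327919 in the FSK_GDNF replicates. The third FSK_GDNF library was thus the shallowest. On the first principal component of log2 expression, which held 51.8% of the variance, the undifferentiated libraries lay between -53.31 and -45.59 and the 6 forskolin libraries between 17.14 and 29.86. The second component held 20.1% and placed the FSK_NGF libraries between 22.12 and 35.52 and the FSK_GDNF libraries between -31.97 and -17.62.

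**Figure D1:**
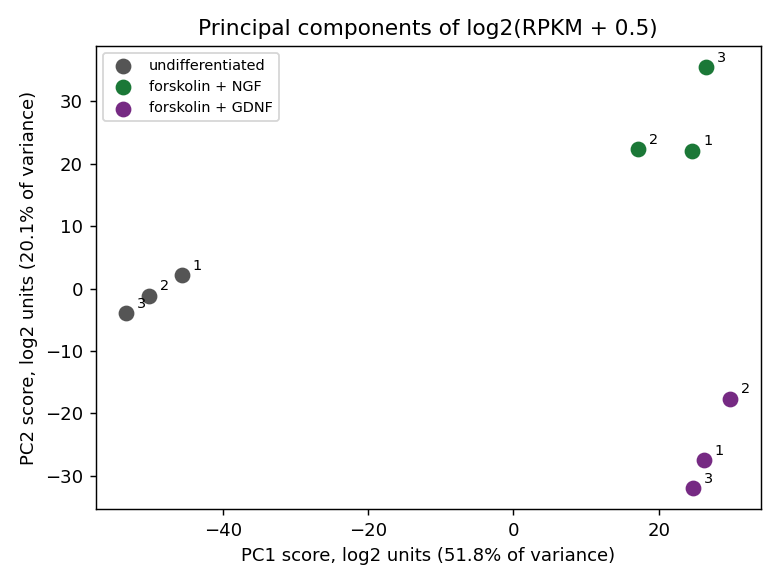
Scores of the 9 libraries on the first and second principal components of log2(RPKM + 0.5), in log2 units. Points are libraries, coloured by group with digits for the replicate, and the first axis (51.8% of the variance) separates undifferentiated from forskolin libraries, the second (20.1%) FSK_NGF from FSK_GDNF.

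The receptors through which both factors act were hardly transcribed in any group. Ntrk1 (ENSRNOG00000013953), the high-affinity NGF receptor, had 37 reads over the 9 libraries and a highest value of 0.0921 RPKM. Ret (ENSRNOG00000014751), the signalling receptor for GDNF, had 30 reads, and its co-receptor Gfra1 (ENSRNOG00000017438) had 9. Gfra2 had 1 read and Gfra3 had 8. The nociceptor genes Calca, Trpv1, P2rx3 and Scn10a had 3, 40, 68 and 2 reads over the 9 libraries, and Tac1 and Scn9a had 0. The neuronal genes Gap43, Isl1 and Pou4f1 had 19, 2 and 17 reads. These genes lay under the filter and were not tested. Ngfr (ENSRNOG00000005392), the low-affinity neurotrophin receptor, rose from 0.0428 ± 0.0266 RPKM in undifferentiated cells to 0.71 ± 0.109 in FSK_NGF and 0.802 ± 0.116 in FSK_GDNF (SD, n = 3 each). Its log2 change was 1.15 (limma adjusted p = 0.000809) and 1.26 (adjusted p = 0.000405). The size depends on the pseudocount at these low values, as it was 0.71 and 0.79 with a pseudocount of 1, 2.51 and 2.67 with 0.1, and 4.02 and 4.23 by voom. The neuronal tubulin Tubb3 stood at 1.59 ± 0.199, 1.33 ± 0.257 and 1.11 ± 0.059 RPKM in undifferentiated, FSK_NGF and FSK_GDNF cells, and the intermediate filament Prph at 13.5 ± 3.05, 10.6 ± 1.16 and 10.8 ± 1.24 RPKM (SD, n = 3). Prph was called without undifferentiated replicate 3, at -0.50 (limma adjusted p = 0.0206) in FSK_NGF and -0.47 (0.0213) in FSK_GDNF. Tubb3 was called in FSK_GDNF with no mean-variance trend (adjusted p = 0.0346) and without short features (0.0455).

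The first comparison asked how expression in FSK_NGF cells differed from that in undifferentiated cells. Among genes that met the naming rule, and on the log2(RPKM + 0.5) scale, the largest rises included those of Pde10a (ENSRNOG00000011310), a cyclic nucleotide phosphodiesterase, from 0.0974 ± 0.0837 to 29.9 ± 1.33 RPKM, and of Dcn (ENSRNOG00000004554), the matrix proteoglycan decorin, from 0.355 ± 0.154 to 33.7 ± 2.81 RPKM (SD, n = 3 each). Rgs2 (ENSRNOG00000003687), a regulator of G protein signalling, rose from 4.97 ± 2.03 to 184 ± 19.3 RPKM. Eya2, Clec3b and Dpt rose by 5.17, 4.84 and 4.70 on the log2 scale. The largest falls on that scale included that of Ltbp2 (ENSRNOG00000012094), a matrix protein of the latent TGF-beta binding protein family, from 115 ± 25.9 to 1.7 ± 0.0175 RPKM. Also among them were the small heat shock protein gene Cryab (ENSRNOG00000010524), from 277 ± 97.6 to 6.69 ± 0.263 RPKM, and Ankrd1 (ENSRNOG00000018598), a target of YAP, from 72.2 ± 37.6 to 1.37 ± 0.201 RPKM. Spp1 (osteopontin), Srpx2 and Adamts12 fell by 4.70, 4.62 and 4.53 on the log2 scale. The order differed in the authors' deposited table. Among genes that the naming rule or the lists name, it put Eya2 at 11.09, Pde10a at 8.25, Il33 at 7.32, Dpt at 7.09 and Dcn at 6.57, and Fbln2 at -6.60 and Ltbp2 at -6.08. The limma adjusted p of the 12 genes with the largest rises and falls under the rule lay between 1.21e-08 for Pde10a and 1.84e-06 for Ankrd1.

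Targets of the transcription factors SRF and YAP/TAZ, many of them actin cytoskeleton genes, fell in FSK_NGF cells in 22 of 24 tested members, with the same count adjusted over the list alone. The median log2 change was -1.32 and camera gave an adjusted p = 1.59e-12, against an adjusted p = 0.648 with an estimated correlation. Tagln (transgelin) fell from 425 ± 190 to 18.8 ± 1.5 RPKM (SD, n = 3). Cyr61, a secreted matrix protein, fell by 3.94 on the log2 scale, and smooth muscle actin (Acta2) fell by 3.33. Genes of cholesterol synthesis and uptake rose in 19 of 24 members, 19 adjusted over the list alone, with a median of 0.54 (camera adjusted p = 8.97e-08, and adjusted p = 0.31 with an estimated correlation). Among them Insig1 rose by 1.41 ± 0.117, Dhcr7 by 0.98 ± 0.107 and Hmgcs1 by 0.94 ± 0.117 (SE). Genes of fatty acid synthesis and lipid storage rose in 16 of 19 members and fell in 1, with the same counts adjusted over the list alone (camera adjusted p = 1.6e-06, and adjusted p = 0.648 with an estimated correlation). Srebf1, the transcription factor of lipid synthesis, rose by 1.15 ± 0.144 and Fasn, the fatty acid synthase, by 0.88 ± 0.135 (SE).

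The cAMP and CREB response list rose in FSK_NGF cells in 11 of 25 members and fell in 5, with the same counts adjusted over the list alone (camera adjusted p = 0.00479, and adjusted p = 0.685 with an estimated correlation). Beside Pde10a and Rgs2, the phosphodiesterases Pde4b and Pde3b rose by 3.80 ± 0.106 and 3.44 ± 0.126 (SE). Extracellular matrix genes fell in 20 of 32 members and rose in 5, with the same counts adjusted over the list alone (camera adjusted p = 0.0106, and adjusted p = 0.706 with an estimated correlation). Lox, the collagen cross-linking oxidase, fell by 3.53 ± 0.118, while tenascin C (Tnc) rose by 3.46 ± 0.11 and Lum by 2.98 ± 0.13 (SE). Markers of fibroblasts and mesenchymal cells rose in 10 of 16 members and fell in 5, with 10 and 6 adjusted over the list alone (camera adjusted p = 0.011, and adjusted p = 0.681 with an estimated correlation). Fbln1 rose from 12.5 to 177 RPKM while Fbln2, another fibulin, fell from 11.6 ± 9.03 to 0.121 ± 0.0119 RPKM. Of these markers, Col1a1 was already abundant in undifferentiated cells, at 811 ± 399 RPKM (SD, n = 3).

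Mitotic genes of the G2/M list fell in FSK_NGF cells in 10 of 38 members, 9 adjusted over the list alone, and none rose (camera adjusted p = 0.0261, and adjusted p = 0.781 with an estimated correlation). Cenpf and Kif23, both needed in cell division, fell by 1.14 ± 0.27 and 0.94 ± 0.123 (SE). The proliferation marker Mki67 stood at 74.9 ± 11.6 RPKM against 144 ± 31.7 in undifferentiated cells (SD, n = 3). Interferon response genes rose in 10 of 20 members, 11 adjusted over the list alone, with Oasl at 1.61 ± 0.236 and Isg15 at 1.43 ± 0.198 (SE; camera adjusted p = 0.0119, and adjusted p = 0.781 with an estimated correlation). Autophagy and lysosome genes rose in 10 of 29 members and fell in 1, also when adjusted over the list alone, with Cd63 at 0.65 and Sqstm1 at 0.60 (camera adjusted p = 0.0264, and adjusted p = 0.717 with an estimated correlation). Neural crest and progenitor markers rose in 6 of 14 members and fell in 1, also when adjusted over the list alone, with Sox9 at 1.61 ± 0.198 (camera adjusted p = 0.0315, and adjusted p = 0.648 with an estimated correlation). Oxidative phosphorylation genes rose in 4 of 27 members and fell in 1, of which 0 and 1 were called when adjusted over the list alone (camera adjusted p = 0.0319, and adjusted p = 0.781 with an estimated correlation). Among all tested genes a larger share, 2649 of 14613, was called higher in FSK_NGF, so this count by itself does not show a rise. With each library's trend with feature length removed, the oxidative phosphorylation, autophagy and neural crest lists were not called (camera adjusted p = 0.0741, 0.0704 and 0.0597). Without undifferentiated replicate 3, 21 G2/M members fell. The oxidative phosphorylation members that rose numbered 1, 8 and 0 without FSK_NGF replicates 1, 2 and 3, and 0, 2 and 0 without undifferentiated replicates 1, 2 and 3.

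In all, 5372 of 14613 genes were called between FSK_NGF and undifferentiated cells, 2649 higher and 2723 lower in FSK_NGF, against 2767 and 2758 after rescaling of the libraries. At a change of at least 2-fold, 468 were higher and 723 lower. The values of the groups did not overlap in 47.66% of the tested genes, against 10% by chance.

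**Figure D2:**
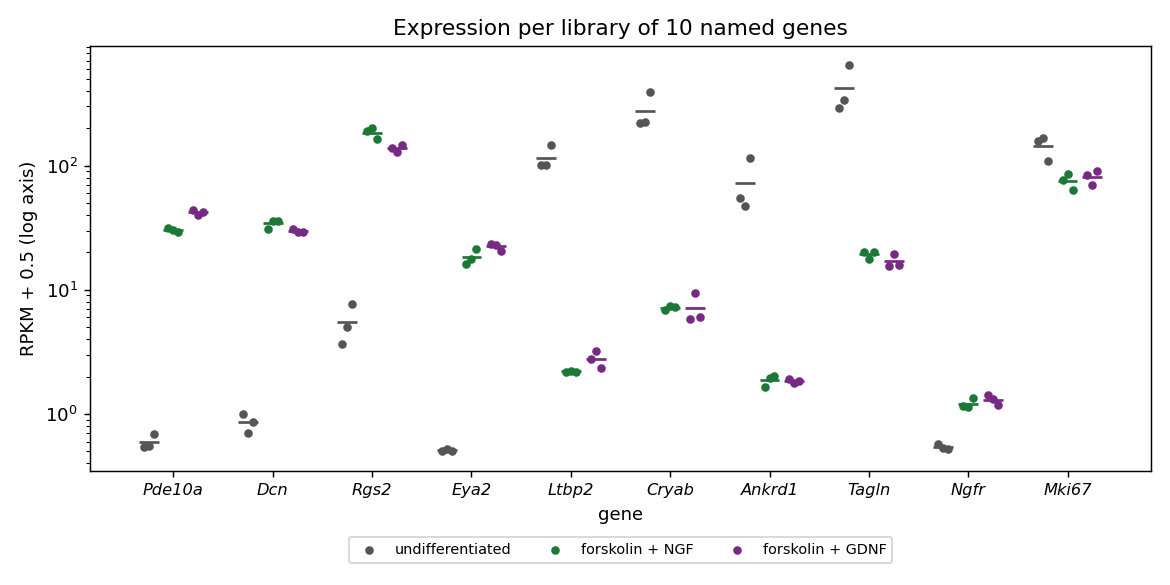
RPKM + 0.5 on a log axis for 10 named genes, with 1 point per library, coloured by group, and a line at the group mean (n = 3 each). Pde10a, Dcn, Rgs2, Eya2 and Ngfr lie higher in the forskolin libraries, and Ltbp2, Cryab, Ankrd1, Tagln and Mki67 lie lower.

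The second comparison set FSK_GDNF against undifferentiated cells. Pde10a rose to 41.8 ± 1.87 RPKM (log2 change 6.15, SE 0.109), Dcn to 29.2 ± 1.18 and Rgs2 to 138 ± 8.73 RPKM (SD, n = 3). Eya2 and Clec3b rose by 5.46 and 4.96 on the log2 scale, and Vcan (ENSRNOG00000029212), the matrix proteoglycan versican, from 12.1 ± 2.45 to 325 ± 42 RPKM. Ltbp2 fell to 2.28 ± 0.43, Cryab to 6.62 ± 2.05, Ankrd1 to 1.34 ± 0.0823 and Spp1 to 12.1 ± 1.01 RPKM. Srpx2 and Tagln fell by 4.72 and 4.57 on the log2 scale. The limma adjusted p of these genes lay between 5.71e-09 for Pde10a and 1.75e-06 for Tagln.

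SRF and YAP/TAZ targets fell in FSK_GDNF cells in 20 of 24 members and rose in 1, with 21 and 1 adjusted over the list alone. The median was -1.40 (camera adjusted p = 7.35e-12, and adjusted p = 0.648 with an estimated correlation), with Cyr61 at -3.81 ± 0.375 and Acta2 at -3.25 ± 0.237 (SE). Cholesterol genes rose in 13 of 24 members and fell in 1, with 18 and 1 adjusted over the list alone (camera adjusted p = 0.00243, and adjusted p = 0.648 with an estimated correlation). Insig1 rose by 0.94 and Srebf2 by 0.90. Fatty acid genes rose in 13 of 19 members and fell in 1, with 16 and 1 adjusted over the list alone (camera adjusted p = 0.000615, and adjusted p = 0.648 with an estimated correlation). Srebf1 rose by 1.32 ± 0.144, while lipoprotein lipase (Lpl) fell by 1.04 ± 0.146 (SE). The cAMP and CREB list rose in 14 of 25 members and fell in 3, with 16 and 5 adjusted over the list alone (camera adjusted p = 0.00189, and adjusted p = 0.681 with an estimated correlation), and Pde4b rose by 3.63 ± 0.106 (SE). G2/M genes fell in 15 of 38 members and none rose, also when adjusted over the list alone (camera adjusted p = 9.27e-05, and adjusted p = 0.781 with an estimated correlation), with Kif23 at -1.09 ± 0.123 and Hmmr at -0.93 ± 0.217 (SE). Without undifferentiated replicate 3, 29 G2/M members fell.

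Axon guidance genes rose in FSK_GDNF cells in 18 of 35 members and fell in 6, also when adjusted over the list alone (camera adjusted p = 0.011, and adjusted p = 0.648 with an estimated correlation). Sema6a rose by 2.38 ± 0.112, the receptor Plxna2 by 2.29 ± 0.197 and the cue Ntn1 by 2.11 ± 0.184, while Sema3e fell by 2.44 ± 0.234 (SE). The same list had 15 members higher and 6 lower in FSK_NGF, also when adjusted over the list alone, and was not called there (camera adjusted p = 0.0963). Fibroblast and mesenchymal markers rose in 10 of 16 members and fell in 4, also when adjusted over the list alone (camera adjusted p = 0.0231, and adjusted p = 0.685 with an estimated correlation), with Dpt at 4.41 and Fbln2 at -4.02. Neural crest markers rose in 6 of 14 members and fell in 1, also when adjusted over the list alone (camera adjusted p = 0.0319, and adjusted p = 0.648 with an estimated correlation), with Sox9 at 2.40 and Snai1 at 1.44. Genes of the unfolded protein and integrated stress response fell in 13 of 26 members and rose in 3, with 13 and 4 adjusted over the list alone (camera adjusted p = 0.0111, and adjusted p = 0.685 with an estimated correlation). Asns, the asparagine synthetase, fell by 1.41 ± 0.186, while the mTOR inhibitor Ddit4 rose by 2.28 ± 0.122 (SE).

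Oxidative phosphorylation genes fell in FSK_GDNF cells in 8 of 27 members and none rose, also when adjusted over the list alone (camera adjusted p = 0.0175, and adjusted p = 0.781 with an estimated correlation). Cytosolic ribosomal protein genes fell in 11 of 42 members and rose in 2, with 9 and 2 adjusted over the list alone (camera adjusted p = 0.0231, and adjusted p = 0.781 with an estimated correlation), among them Rpl30 at -0.76 ± 0.144 and Rpl5 at -0.65 ± 0.132 (SE). Without FSK_GDNF replicate 3 neither list was called, with a camera adjusted p = 0.115 for the first and 0.117 for the second. With the trend with feature length removed, the ribosomal list was not called (camera adjusted p = 0.0597). Oxidative phosphorylation members that fell numbered 5 without FSK_GDNF replicate 1 and without undifferentiated replicate 1 or 2, and ribosomal ones 6 without FSK_GDNF replicate 1 or undifferentiated replicate 2. Of the recovered reads, features with mitochondrial symbols took 1.046%, 1.184% and 1.596% in FSK_GDNF replicates 1 to 3. In undifferentiated libraries they took 0.303% to 0.745%. Genes without recovered reads, possibly the most abundant ones, are left out of these shares. In all, 6088 of 14613 genes were called, 3418 higher and 2670 lower in FSK_GDNF, of which 840 and 476 changed at least 2-fold. Higher calls were not the majority after rescaling of the libraries (3142 higher and 3207 lower), with the length trend removed (3127 and 3262) or in the authors' deposited table (3359 and 3455). The values did not overlap in 54.55% of the tested genes, against 10% by chance.

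**Figure D3:**
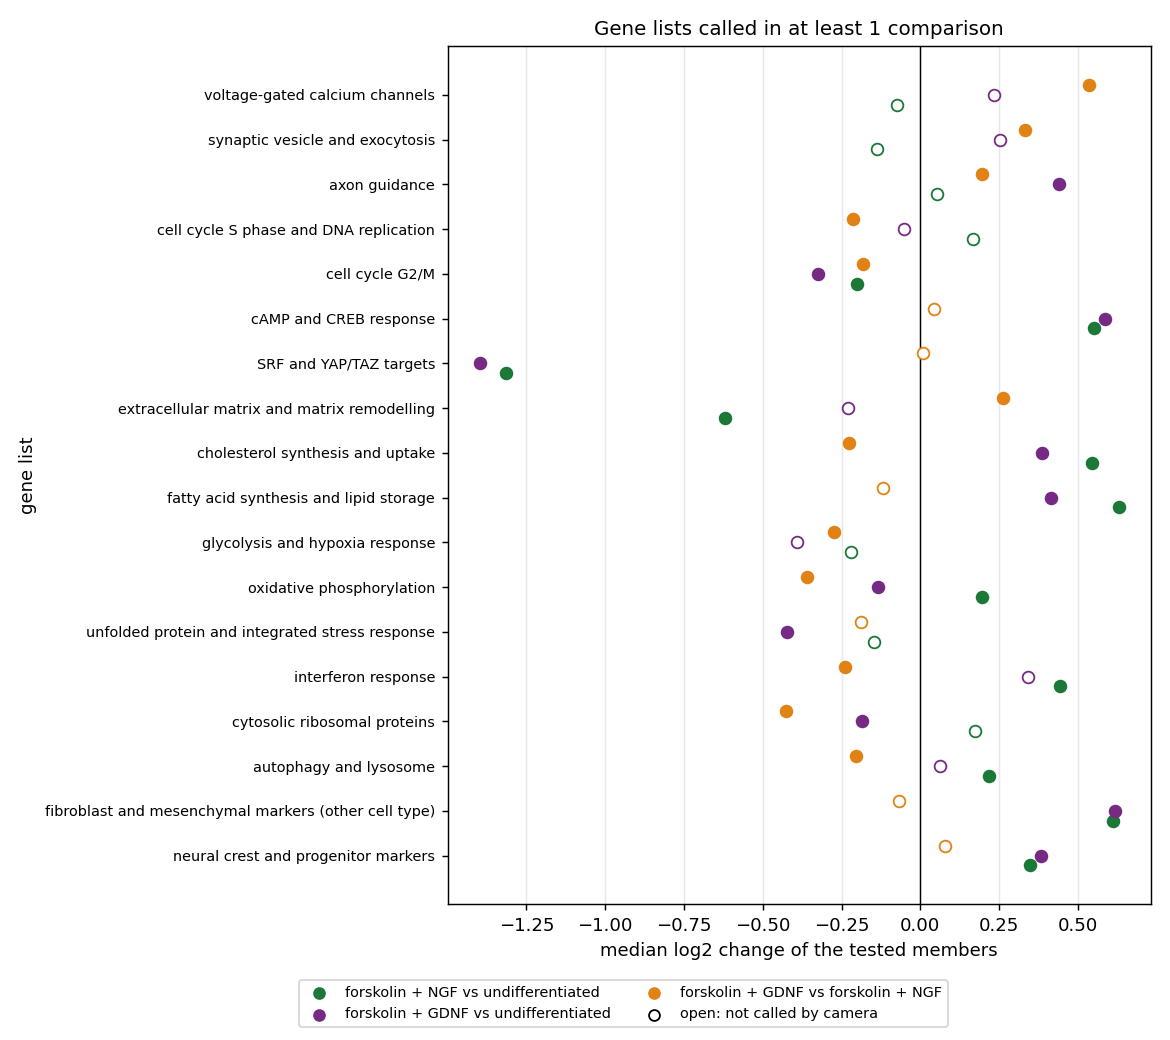
Median log2 change of the tested members of each gene list that camera called in at least 1 comparison at the preset correlation. Green, purple and orange points are FSK_NGF against undifferentiated, FSK_GDNF against undifferentiated and FSK_GDNF against FSK_NGF, open points were not called, and SRF and YAP/TAZ targets lie lowest at -1.32 and -1.40.

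Calls were shared between the comparisons against undifferentiated cells. Of the tested genes, 1819 were higher and 1522 lower in both forskolin groups, and 98 were called in opposite directions. Independent lists of these sizes would share 620 and 498 genes, and unchanged groups simulated with shared controls had 0 shared calls in each of 20 draws. That count of 0 follows from the lack of change and does not measure what shared controls add to the overlap. Across genes, which are not independent replicates, the log2 changes of both comparisons had a Pearson r of 0.788, against a mean of 0.498 in the simulation, which arises from the shared controls alone. Their covariance was 0.3354, against 0.024 simulated, a difference of 0.3114. With 3 undifferentiated libraries the controls cannot be split into parts that keep enough libraries, so part of the excess overlap may come from the shared controls.

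The third comparison set FSK_GDNF against FSK_NGF, which share forskolin, serum and time and differ, per the labels, in the growth factor. Whether they also differ in culture or plating day is not stated. The direction of this comparison depends on how the column codes were read, and under the other reading every sign in it changes. Nuclear genes of the respiratory chain and genes of the ribosome were among those lower in FSK_GDNF, while 8 of 13 mitochondrially encoded protein genes, a class chosen after its values were seen, were higher at a median of 1.22. Nuclear oxidative phosphorylation genes fell in 13 of 27 members, 21 adjusted over the list alone, with a median of -0.36 (camera adjusted p = 4.52e-09, and adjusted p = 0.648 with an estimated correlation). Ndufb5, a complex I subunit, stood at 49.7 ± 6.08 against 78.1 ± 5.16 RPKM (log2 change -0.65, SE 0.114, limma adjusted p = 0.00566). Ribosomal protein genes fell in 16 of 42 members and rose in 1, with 21 and 1 adjusted over the list alone, at a median of -0.43 (camera adjusted p = 5.06e-07, and adjusted p = 0.648 with an estimated correlation). Rps8, Rps23 and Rpl7 fell by 0.63 ± 0.115, 0.61 ± 0.129 and 0.59 ± 0.096 (SE). S phase genes fell in 9 of 36 members and none rose, 11 adjusted over the list alone (camera adjusted p = 0.00338, and adjusted p = 0.681 with an estimated correlation), with the replication clamp Pcna at -0.54 ± 0.095 and Tyms at -0.50 ± 0.088 (SE). The G2/M list had a median of -0.18 (camera adjusted p = 0.0315, and adjusted p = 0.781 with an estimated correlation), with 0 of 38 members called by limma, also when adjusted over the list alone. At an unadjusted p under 0.05, 3 of its members were higher and 5 lower, and voom on the recovered reads called 1 higher and 1 lower. Its members with the highest RPKM, Top2a and Cdk1, had log2 changes of -0.39 and -0.35, and a limma fit on the compared groups only called Cdk1 (adjusted p = 0.0469). The authors' deposited table listed both as lower, at -0.44 and -0.39 (the authors' adjusted p = 0.000626 and 0.00209). The counts leaned on single libraries. Without FSK_GDNF replicate 1, 3 oxidative phosphorylation, 4 ribosomal and 4 S phase genes fell, and without FSK_NGF replicate 1 these numbered 8, 6 and 5, with 1 G2/M gene higher. Without FSK_GDNF replicate 3, 6 oxidative phosphorylation and 5 ribosomal genes fell, and without FSK_NGF replicate 3, 8 oxidative phosphorylation genes fell.

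Cholesterol genes were lower in FSK_GDNF than in FSK_NGF in 9 of 24 members and higher in 1, with 11 and 1 adjusted over the list alone (camera adjusted p = 0.00338, and adjusted p = 0.648 with an estimated correlation), with Msmo1 at -0.50 ± 0.095 (SE). Autophagy and lysosome genes fell in 9 of 29 members and rose in 1, with 10 and 1 adjusted over the list alone (camera adjusted p = 0.00243, and adjusted p = 0.681 with an estimated correlation). Ctsl, a lysosomal protease, fell by 0.47 ± 0.088 and the kinase Ulk1 rose by 0.67 ± 0.099 (SE). Glycolysis and hypoxia genes fell in 6 of 23 members and rose in 1, with 6 and 2 adjusted over the list alone (camera adjusted p = 0.038, and adjusted p = 0.717 with an estimated correlation). Pgk1 fell by 0.54 ± 0.098 and Vegfa rose by 0.59 ± 0.08 (SE). Of the interferon list, Bst2 was higher and Gbp2 lower among 20 members, with 1 higher and 0 lower adjusted over the list alone, and the list's median was -0.24 (camera adjusted p = 0.0447, and adjusted p = 0.781 with an estimated correlation). Without FSK_GDNF replicate 3 the glycolysis and interferon lists were not called (camera adjusted p = 0.119 and 0.123). They were not called with the length trend removed either (camera adjusted p = 0.167 and 0.107), nor was the glycolysis list after rescaling of the libraries (camera adjusted p = 0.0611). The call of Gbp2 was lost when any 1 of the 6 libraries compared was left out, at an adjusted p of up to 0.0871. The cholesterol genes that fell numbered 1, 5 and 2 without FSK_GDNF replicates 1, 2 and 3, and 4 and 3 without FSK_NGF replicates 1 and 3. The autophagy genes that fell numbered 2 without FSK_GDNF replicate 1 and 5 without FSK_GDNF replicate 3, FSK_NGF replicate 1 or FSK_NGF replicate 3. The glycolysis genes that fell numbered 1 without FSK_GDNF replicate 1, FSK_GDNF replicate 3 or FSK_NGF replicate 1, and 3 without FSK_NGF replicate 3.

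Genes of neuronal signalling were among those higher in FSK_GDNF than in FSK_NGF. Voltage-gated calcium channel genes rose in 4 of 9 tested members, 5 adjusted over the list alone, with a median of 0.54 (camera adjusted p = 0.00752, and adjusted p = 0.648 with an estimated correlation). Cacna1a, which encodes a P/Q-type channel pore, stood at 9.12 ± 0.719 against 3.75 ± 0.179 RPKM (log2 change 1.18, SE 0.102, limma adjusted p = 0.000632), and Cacnb1 rose by 0.90 ± 0.117 (SE). The other called members did not hold throughout. Cacna1g was lost without FSK_GDNF replicate 1 (limma adjusted p = 0.0789) and with the length trend removed (0.103). Cacna1c was lost without FSK_GDNF replicate 1, 2 or 3 or FSK_NGF replicate 2 or 3 (adjusted p from 0.0544 to 0.086) and with the length trend removed (0.135). Synaptic vesicle and exocytosis genes rose in 8 of 18 members and none fell, also when adjusted over the list alone (camera adjusted p = 0.011, and adjusted p = 0.648 with an estimated correlation). The syntaxin gene Stx1b rose by 1.24 ± 0.106 and Vamp2, which encodes a vesicle SNARE protein, by 0.90 ± 0.093 (SE). Against undifferentiated cells, synaptic genes rose in 3 members and fell in 7 in FSK_NGF, and rose in 7 and fell in 4 in FSK_GDNF, with 3 and 8, and 8 and 4, adjusted over the list alone. Calcium channel genes rose in 1 and fell in 2 in FSK_NGF and rose in 3 in FSK_GDNF, with the same counts adjusted over the list alone. Stx1b stood at 4.63 ± 0.141 RPKM in undifferentiated cells, 2.16 ± 0.15 in FSK_NGF and 5.79 ± 0.537 in FSK_GDNF (SD, n = 3), and Cacnb1 fell by 0.77 in FSK_NGF. Axon guidance genes rose in 6 of 35 members and none fell, also when adjusted over the list alone (camera adjusted p = 0.0222, and adjusted p = 0.648 with an estimated correlation), with Sema4c at 0.67 ± 0.101 (SE). Among all tested genes a similar share, 2174 of 14613, was called higher in FSK_GDNF. The number of axon guidance genes that rose thus does not by itself show a rise of the list. Extracellular matrix genes rose in 10 of 32 members and none fell, also when adjusted over the list alone (camera adjusted p = 0.0279, and adjusted p = 0.781 with an estimated correlation), with the proteoglycan Bgn at 0.77 ± 0.124 (SE). With each library's trend with feature length removed, the axon guidance and matrix lists were not called (camera adjusted p = 0.229 and 0.196). Without FSK_GDNF replicate 1, 2 calcium channel, 5 synaptic, 2 axon guidance and 4 matrix genes rose. Without FSK_NGF replicate 2, 3 axon guidance and 6 matrix genes rose, and without FSK_GDNF replicate 3, 6 matrix genes.

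Among features that met the naming rule, which passes over many symbols, those with the largest differences on the log2(RPKM + 0.5) scale between FSK_GDNF and FSK_NGF were mostly small RNAs and pseudogenes. The vault RNA feature rose from 41.7 ± 37.8 to 242 ± 50.4 RPKM (log2 change 2.86, SE 0.481, limma adjusted p = 0.0047), and Rn50_X_0752.3 from 111 ± 39.9 to 472 ± 63.7 RPKM (SD, n = 3). A pair of 5S_rRNA features rose by 2.25 and 2.07, and a 5_8S_rRNA feature by 2.18. A feature that the file names by a sequence accession, counted here as mitochondrial by its symbol, rose by 2.57. These rises were each lost without FSK_GDNF replicate 1 and without FSK_GDNF replicate 3. Some were also lost without FSK_GDNF replicate 2 or FSK_NGF replicate 1 or 2. Their highest limma adjusted p over the alternatives lay between 0.064 and 0.126. Sec61-ps fell by 1.13 ± 0.257 (SE, adjusted p = 0.0153). The falls of Hmgb2 (-1.59), Rps15al2 (-1.37), U7 (-1.18), Rn50_X_0699.2 (-1.17) and Gsta1 (-0.81) were called at an adjusted p between 0.0117 and 0.0494. Those of Hmgb2, Rps15al2 and U7 were each lost without FSK_GDNF replicate 1 and without FSK_GDNF replicate 3, and also without FSK_NGF replicate 3 and, in some, FSK_NGF replicate 1 or 2 or FSK_GDNF replicate 2. Rn50_X_0699.2 was lost without FSK_GDNF replicate 1 (adjusted p = 0.051) and Gsta1 without FSK_GDNF replicate 3 (0.0536). The highest adjusted p of these 5 over the alternatives lay between 0.051 and 0.147. Without FSK_NGF replicate 3, the change of the feature named by an accession was 1.47, that of Hmgb2 -0.92 and that of Rps15al2 -0.86. Features of 300 nt or less had a median log2 change of 0.44, with 293 of 1692 higher and 36 lower, and genes over 6000 nt a median of 0.22, with 340 of 1002 higher and 11 lower. Genes between 600 and 1000 nt had a median of -0.14, with 87 of 935 higher and 147 lower. Of the recovered reads, features with mitochondrial symbols took 1.046% to 1.596% in FSK_GDNF libraries and 0.282% to 0.672% in FSK_NGF libraries. These shares are not limited to protein genes. They leave out genes without recovered reads, possibly the most abundant ones.

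**Figure D4:**
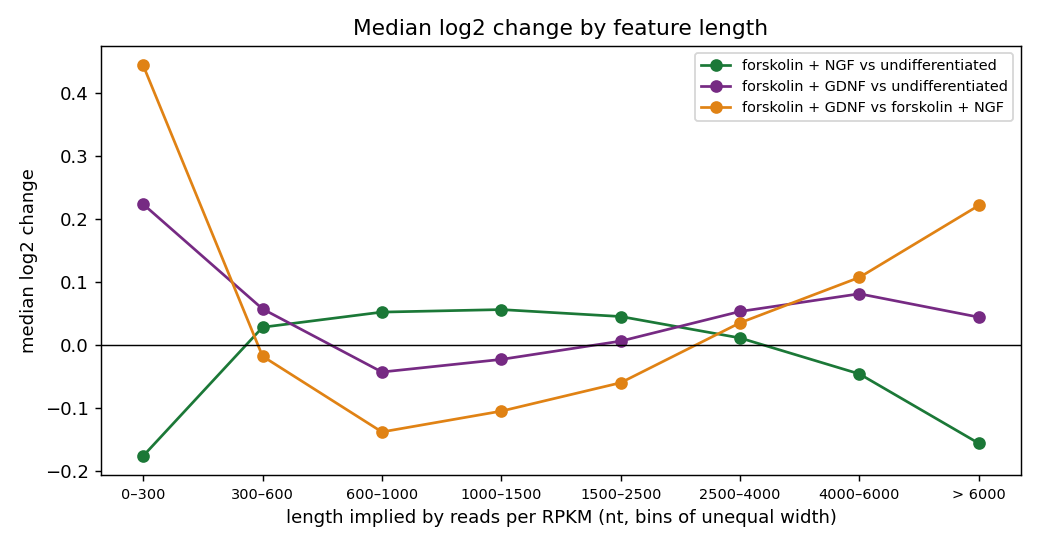
Median log2 change of all tested features in 8 bins of feature length, in nt, as implied by the ratio of reads to RPKM, with 1 line for each of the 3 comparisons. Between FSK_GDNF and FSK_NGF the median is 0.44 at 300 nt or less, -0.14 from 600 to 1000 nt and 0.22 over 6000 nt.

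In all, 3420 of 14613 genes were called between FSK_GDNF and FSK_NGF, 2174 higher and 1246 lower in FSK_GDNF, and at least 2-fold changes were seen in 404 and 18. The count was 1151 without FSK_GDNF replicate 1, 1994 without FSK_GDNF replicate 3 and 2254 without FSK_NGF replicate 1. The share of calls that were higher in FSK_GDNF was 63.57%, against 50.0% after rescaling the libraries and 48.1% in the authors' deposited table. The values of the groups did not overlap in 43.12% of the tested genes, against 10% by chance.

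Lists of sensory neuron genes were not called as a whole against undifferentiated cells, and most of their members lay under the filter. Of 18 peptidergic nociceptor markers in the file, 3 were tested, and of 24 non-peptidergic markers, 7. Bdnf, a neurotrophin, fell by 1.64 in FSK_NGF and 1.61 in FSK_GDNF, and Sstr2, a somatostatin receptor, rose by 0.92 and 1.46. Of the peptidergic markers 1 rose and 2 fell in FSK_NGF, and 1 rose and 1 fell in FSK_GDNF. Of the non-peptidergic markers 1 rose and 4 fell in FSK_NGF, and 3 rose and 4 fell in FSK_GDNF. Both lists had the same counts adjusted over the list alone. Among non-peptidergic markers the angiotensin receptor gene Agtr1a fell by 1.46 and 1.85. Neuronal cytoskeleton and axon genes rose in 4 of 16 members and fell in 5 in FSK_NGF, and rose in 7 and fell in 4 in FSK_GDNF, with 4 and 6, and 7 and 5, adjusted over the list alone. Dpysl3 and Basp1, both growth cone proteins, fell by 2.47 and 2.61 in FSK_NGF. The authors' deposited table listed them as lower in FSK_GDNF too, at -2.46 and -2.31. Map2, a dendritic microtubule protein, rose by 1.41 in FSK_NGF and 1.61 in FSK_GDNF. Of 8 tested sensory neuron transcription factors, 2 rose and 1 fell in FSK_NGF and 4 rose in FSK_GDNF, with the same counts adjusted over the list alone, and Maf rose by 0.92 and 1.33. Without undifferentiated replicate 1, 3 of these factors rose and 2 fell in FSK_NGF. Axon regeneration genes rose in 5 of 16 members and fell in 6 in FSK_NGF, and rose in 6 and fell in 6 in FSK_GDNF, with 6 and 6, and 7 and 6, adjusted over the list alone. Among them Klf4 rose by 1.72 and 1.63 and Arg1 fell by 1.75 and 2.15. The sodium channel list had 1 tested member, Scn1b, at log2 changes of 0.41 (adjusted p = 0.0595) and 0.30 (adjusted p = 0.147). In FSK_NGF it was called without FSK_NGF replicate 2 (adjusted p = 0.041), without undifferentiated replicate 1 (0.037), after rescaling (0.0445), without short features (0.0392) and by voom (0.0438). Potassium and HCN channel genes rose in 2 of 8 and fell in 2 in FSK_NGF, and rose in 3 and fell in 1 in FSK_GDNF, also when adjusted over the list alone, and Hcn2, a pacemaker channel, rose by 0.95 and 1.14. The camera adjusted p of these lists against undifferentiated cells lay between 0.134 and 0.99.

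Of the markers of other cell types, 16 of 19 fibroblast and mesenchymal markers in the file passed the filter. Of 18 endothelial and immune markers in the file, 6 were tested, and 3 fell in FSK_NGF and 1 in FSK_GDNF, also when adjusted over the list alone. Of the calls in FSK_NGF, Fcer1g was lost without FSK_NGF replicate 3 or undifferentiated replicate 1, 2 or 3 (limma adjusted p from 0.0891 to 0.106), and Csf1r without FSK_NGF replicate 1 or 3 or undifferentiated replicate 2 or 3 (0.102 to 0.129). The count was 1 without FSK_NGF replicate 3 and without undifferentiated replicate 2. The call of Cd68 in FSK_GDNF was lost without FSK_GDNF replicate 2 (limma adjusted p = 0.0534), and 2 markers fell there without undifferentiated replicate 1. Among them Cd68 stood at 1.88 ± 0.303 RPKM in undifferentiated cells, 0.392 ± 0.0893 in FSK_NGF and 1.03 ± 0.173 in FSK_GDNF (SD, n = 3). Of 19 Schwann and satellite glia markers 8 were tested, and 2 rose and 2 fell in FSK_NGF and 2 rose in FSK_GDNF, with 2 and 3, and 2, adjusted over the list alone. Without FSK_NGF replicate 3, 1 rose and 1 fell in FSK_NGF. Glul, glutamine synthetase, rose by 1.67 in FSK_NGF and 1.39 in FSK_GDNF, while Apoe fell by 0.61 in FSK_NGF. Of 8 tested proprioceptor and mechanoreceptor markers, Spp1 was the called member in FSK_NGF, and 1 member rose beside it without FSK_NGF replicate 2 or undifferentiated replicate 3. In FSK_GDNF 3 of them rose and 1 fell, and 2 were higher in FSK_GDNF than in FSK_NGF, with the same counts adjusted over the list alone. The remaining lists were not called by camera against undifferentiated cells. ERK and MAPK output genes rose in 4 of 23 members and fell in 7 in FSK_NGF, with 4 and 8 adjusted over the list alone, and rose in 7 and fell in 5 in FSK_GDNF, with 7 and 7 adjusted over the list alone. Among them Phlda1 rose by 2.04 and 2.49, the ERK inhibitor Spry2 rose by 1.94 and 2.23, and cyclin D1 (Ccnd1) fell by 1.97 in FSK_NGF and fell by 1.89 in FSK_GDNF. Inflammatory genes rose in 7 of 16 members and fell in 3 in FSK_NGF, and rose in 6 and fell in 2 in FSK_GDNF, with 7 and 4, and 7 and 3, adjusted over the list alone, with the chemokine Cxcl1 at 2.70 and 2.58. Purinergic, acid-sensing and Piezo channel genes rose in 2 of 10 members and fell in 3 in FSK_NGF, and rose in 3 in FSK_GDNF, with 2 and 4, and 3, adjusted over the list alone, and P2rx2, an ATP receptor gene, fell by 1.31 in FSK_NGF. Between FSK_GDNF and FSK_NGF 3 of them were higher, also when adjusted over the list alone, against 0 without FSK_GDNF replicate 1 and 1 without FSK_NGF replicate 1. TRP channel genes rose in 1 of 6 members and fell in 1 in FSK_NGF, and rose in 3 and fell in 1 in FSK_GDNF, also when adjusted over the list alone, with Trpv4 at 0.93 and 1.26. Opioid, cannabinoid and inflammatory mediator receptor genes rose in 3 of 14 members and fell in 4 in FSK_NGF, and rose in 5 and fell in 3 in FSK_GDNF, also when adjusted over the list alone. The sphingosine phosphate receptor gene S1pr3 fell by 2.49 in FSK_NGF and fell by 2.54 in FSK_GDNF. Targets of p53 rose in 9 of 23 members and fell in 6 in each forskolin group, with 10 and 7 in FSK_NGF and 9 and 8 in FSK_GDNF adjusted over the list alone. Some lists called in another comparison were not called by camera here. Unfolded protein and stress response genes rose in 3 of 26 members and fell in 8 in FSK_NGF, with 3 and 9 adjusted over the list alone, and rose in 1 and fell in 6 without undifferentiated replicate 1. Glycolysis and hypoxia genes rose in 5 of 23 and fell in 4 in FSK_NGF, and rose in 5 and fell in 10 in FSK_GDNF, with 6 and 6, and 6 and 11, adjusted over the list alone. In FSK_GDNF, matrix genes rose in 7 of 32 and fell in 11, interferon genes rose in 8 of 20 and fell in 2, and autophagy genes rose in 3 of 29 and fell in 5. Adjusted over the list alone these were 7 and 13, 8 and 2, and 3 and 5, and without FSK_GDNF replicate 1 autophagy genes rose in 1 and fell in 4. In 12 of the 105 tests the median, the mean and the direction of camera differed in sign, and none of these 12 was called.

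The authors' deposited tables listed 5523, 6814 and 4311 genes for the comparisons of FSK_NGF with undifferentiated, FSK_GDNF with undifferentiated and FSK_GDNF with FSK_NGF. Of these, 5204, 6407 and 4260 passed the filter, and the limma test also called 91.8%, 87.0% and 70.0% of those. Every listed gene that was tested had the same sign in the authors' deposited table and in the limma fit. Both come from the same libraries, and the direction of the deposited comparisons was checked against the RPKM values, so this is not independent support.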

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

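Alternatives chosen only after the results were seen were voom on recovered reads, leaving out features of 300 nt or less, removing the length trend and, for the lists, leaving out FSK_GDNF replicate 3. A 2-fold threshold left 1191, 1316 and 422 calls of 5372, 6088 and 3420 for FSK_NGF against undifferentiated, FSK_GDNF against undifferentiated and FSK_GDNF against FSK_NGF, by construction. Leaving out 1 library in turn gave 4005 to 5710, 4575 to 5824 and 1151 to 3114 calls, and 2698 to 3559 shared calls against 3341 with all libraries. In the last comparison the count fell by more than 1.5 times without FSK_GDNF replicate 1 (1151), FSK_GDNF replicate 3 (1994) or FSK_NGF replicate 1 (2254), where fewer samples were tested. With the replicate number as a block the calls were 4416, 5239 and 2235, and the shared calls 2750. Same-numbered libraries did not deviate together (correlations of deviations from -0.337 to 0.096, and 1 of 9 libraries correlated best with its own number in another group), so the numbers are not taken to pair the samples. The highest correlations joined different numbers, 0.315 for FSK_NGF replicate 2 with FSK_GDNF replicate 3 and 0.206 for FSK_NGF replicate 3 with FSK_GDNF replicate 2. Whether such libraries shared a batch was not tested. The counts under pseudocounts of 0.1 and 1, other filters, rescaling, no trend, a fit on the compared groups, voom (5751, 6450 and 3629), the leaving out of short features and the removal of the length trend stayed within 1.5 times the main count. Rescaling moved the median of all genes by 0.049 or less on the log2 scale, and it moved the share of calls higher in FSK_GDNF than in FSK_NGF from 63.6% to 50.0%. Removing the length trend moved it to 47.9%.

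Of 105 list tests 34 were called, against 34 with the block, 33 after rescaling, 29 with the length trend removed and 30 without FSK_GDNF replicate 3. With the length trend removed, 9, 10 and 10 lists were called in the 3 comparisons, against 11, 11 and 12. For FSK_NGF against undifferentiated and FSK_GDNF against FSK_NGF, the counts fell by less than the losses given above. Some lists not called in the main test were therefore called in those comparisons. With an estimated correlation 0 were called, at a lowest adjusted p of 0.31. The estimates exceeded the preset 0.01 in lists such as G2/M (0.608), interferon (0.498) and SRF and YAP/TAZ (0.442). They came closer to it for cholesterol genes (0.037) and were below it in others, such as neurotrophic factor receptors (-0.09). A large estimate was not needed for a higher p. Between FSK_GDNF and FSK_NGF, the unadjusted camera p of sensory neuron transcription factors went from 0.0279 to 0.0633 at an estimate of -0.072. In FSK_NGF against undifferentiated, that of cholesterol genes went from 3.42e-09 to 0.00295 at 0.037. The p53 list, at an estimate of 0, hardly moved (0.53 and 0.516 between FSK_GDNF and FSK_NGF). How much of the loss of calls the size of the estimates accounts for was not tested. Of 355 calls of named genes, 80 were lost under at least 1 alternative and 0 changed sign. The log2 change moved by over 1.5 times in 42 of the 355 by voom, 20 and 6 with pseudocounts of 0.1 and 1, 11 with the length trend removed and 5 without FSK_NGF replicate 3. The number of calls shared with the authors' deposited tables, in the same direction, was 13330, and 12621 without the filter. Genes under the filter were not tested, and the third FSK_GDNF library had the fewest reads, 11327919.

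For each comparison the 6 libraries can be split into groups of 3 in 10 ways, so the share of splits with as many calls cannot fall below 0.1. The real split alone (1 of 10) gave as many calls, with 5372, 6088 and 3420 against at most 0 in the other splits. At an unadjusted p under 0.05 limma found 6834, 7353 and 5593 genes in the real splits and at most 1419, 633 and 2099 in the others. Each other split mixes libraries of both groups, so differences between the groups add to the spread there. The low counts in those splits therefore do not show what unchanged groups would give.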

Other observations

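The gene classes below, the small RNA test and the tests on fibroblasts and histone genes were chosen only after the values were seen. Replication-dependent histone genes were higher in both forskolin groups. Of 37 tested, 33 rose in FSK_NGF (median log2 change 1.21, quartiles 1.03 and 1.32) and 28 in FSK_GDNF (median 0.87), and none fell. Between FSK_GDNF and FSK_NGF limma called 0 of them, at a median of -0.30, with 1 lower at an unadjusted p under 0.05 and 0 called by voom. After rescaling, 33 rose in FSK_NGF and 26 in FSK_GDNF, and 1 was lower in FSK_GDNF than in FSK_NGF. Their near-identical copies may share reads. Short transcripts as a class did not move with them, since 1199 other named genes in the same length range had medians of 0.05 and -0.04, so that the smaller of the gaps was -0.917. A larger share of cells in S phase is a candidate explanation that these data leave open, although Mki67 fell by 0.92 and 0.81 and 10 and 15 of 38 G2/M genes fell (21 and 29 without undifferentiated replicate 3) with none higher. Of 36 S phase genes, 12 rose and 2 fell in FSK_NGF (7 and 1 without FSK_NGF replicate 3) and 5 rose and 4 fell in FSK_GDNF, at medians of 0.166 and -0.052 (quartiles -0.149 and 0.139 in FSK_GDNF), and the test could not decide. How histone transcripts without a poly(A) tail are kept in total RNA libraries was not tested.

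Among 21 tested Hox genes, which mark position along the body axis, 12 were higher in FSK_GDNF than in FSK_NGF and none lower, at a median of 0.56. After rescaling, 11 were higher and 1 lower. Hoxc6 stood at 27.4 ± 1.25 RPKM in undifferentiated cells, 32.8 ± 1.74 in FSK_NGF and 78.1 ± 5.27 in FSK_GDNF, and Hoxb5 at 6.33 ± 0.689, 4.05 ± 0.409 and 12.2 ± 0.33 RPKM (SD, n = 3 each). Hoxd13 stood at 12.5 ± 1.79, 9 ± 0.94 and 6.96 ± 0.125 RPKM. Of the 13 mitochondrially encoded protein genes, 8 were higher in FSK_GDNF than in FSK_NGF, with a median of 1.22 (7 after rescaling), while Mt-co1 stood at 2450 ± 535 and 2400 ± 162 RPKM in the respective FSK_NGF and FSK_GDNF libraries.

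The 69 ribosomal protein and oxidative phosphorylation genes together had a median of -0.41 between FSK_GDNF and FSK_NGF. A trend with gene length was not the whole cause, as the median was -0.389 (quartiles -0.472 and -0.267) with each library's length trend removed. The low depth of the third FSK_GDNF library was not the whole cause either, since the median was -0.348 (quartiles -0.452 and -0.212) without it. A larger share of nuclear RNA in the FSK_GDNF libraries is a candidate explanation that remains open. Nuclear small RNA features had a median of 0.474 and cytoplasmic ones 0.598, a difference of -0.125, but annotated copies of either kind can lie in introns and take up reads of unspliced RNA, which could not be separated here. A difference in growth factor remains open and untested against these, because it separates the groups by design. The labels do not say whether both groups came from the same cultures or plating days. A difference of that kind cannot be told apart from the growth factor.

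The rise of Dcn, Dpt, Lum and Fbln1 in both forskolin groups might come from fibroblasts in the cultures. Other fibroblast and mesenchymal markers went both ways in FSK_NGF and FSK_GDNF, as Twist2 rose by 2.35 and 2.67, Prrx1 by 0.83 and 1.06, Pdgfrb by 0.54 and 0.86 and Pdgfra by 0.68 and 0.70 on the log2 scale, while Fbln2 stood at -4.04 and -4.02 and S100a4 at -0.63 and -1.05. Means in undifferentiated, FSK_NGF and FSK_GDNF libraries were 11.1, 5.64 and 4.96 RPKM for Thy1, 596, 416 and 376 for Vim, 811, 326 and 711 for Col1a1 and 1760, 1040 and 1320 for Col3a1, and the levels of Vim and both collagens could hide a small share of fibroblasts. In the same order, Col6a1 stood at 97.1, 75.8 and 96.8 RPKM and Col6a2 at 87.9, 102 and 130. Twist1 stood at 5.52, 10 and 8.19 RPKM and Pdpn at 22.1, 31.3 and 28.9. Against fibroblasts as the whole source, Mmp2 and Col6a3, which fibroblasts transcribe abundantly, reached at most 1.31% of the RPKM of Dcn in the 6 forskolin libraries. Their means were 0, 0.0997 and 0.106 RPKM, and 0.129, 0.264 and 0.318 RPKM, in the same order of groups. Fap and Mfap5 stayed at or below 0.0294 RPKM in all 9. These genes were picked among markers that went both ways, and Col6a3 was low beside abundant Col6a1 and Col6a2, so they do not settle the question. A small share of fibroblasts, cells that lack these transcripts and other cell types were not excluded, and whether the rise lies in the 50B11 cells themselves was not tested.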
